A study of Homo sapiens with 12 samples.

How the data were processed

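KMT2D binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF7, an estrogen receptor-positive human breast cancer cell line carrying a doxycycline-inducible short hairpin against SMYD2. Per the labels, cells were kept with vehicle or 1 ug/mL doxycycline for 3 days, seeded, and given vehicle or 1 uM alpelisib 24 h later for 8 h. The 12 samples comprised 4 KMT2D libraries, 1 for each combination of the 2 agents, 2 input samples, and 6 CUT&RUN samples of cells transfected with empty vector or FLAG-tagged SMYD2, 3 of each. The peak lists of the 4 KMT2D libraries were analysed; the input and CUT&RUN samples were not analysed here.

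The deposited lists were in MACS2 narrowPeak layout, 1 list per library, so peaks were called per sample and not on pooled samples. Per the submitters' processing notes, Bowtie2 2.4.2, SAMtools 1.18 and MACS2 2.2.7.1 were used. Per the names of the deposited lists, reads were sorted, duplicates were removed, peaks were called against input, and blacklisted regions were taken out. The deposited fold of each peak is the enrichment of its summit over the local background, a linear ratio written by MACS2 with 1 added to both. Summits given below as times the background carry no such addition and use the genome background, so they are larger than the fold of the same peak. The deposited −log10 p and −log10 q values belong to the same summit. The deposited score of each peak is 10 times its −log10 p, so peaks had been called at a p of 0.001. The lowest fold in the 4 lists was 2.00 and the lowest −log10 q was 1.06, which matches a filter on a fold of 2 and a −log10 q of 1 named for the lists. These values are the authors' own and were used to describe, rank and filter peaks and to recover fragments and background. A deposited fold depends on the depth and local background of its own library, so folds printed for 2 lists are not a measured difference between conditions.

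The submitters' processing notes name the build hg18, while the lists carry the name hg38. The coordinates settled this: the last peak on chromosome 17 ended at 83247382, beside the last annotated gene end of GRCh38.p14 at 83240804. Peaks of the vehicle library lay at the gene ends of 7898 protein-coding genes, against a mean of 2016 over 100 random placements of the same peaks. All positions are therefore given in hg38, counted from 1. Chromosomes 1 to 22 and X held every deposited peak.

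The reference used here gave the start and end of each gene but no strand, exon or sequence. Promoters, fixed in the plan as 1 kb around transcript starts, were therefore replaced by gene ends, defined as 1 kb either side of both ends of a protein-coding gene. A gene end peak can thus lie at the start or at the end of a gene, and transcript starts inside a gene are not counted. Peak summits were classed as gene end, gene body or intergenic in place of promoter, exon and intron. Motif shares and the random lists matched on GC content, both planned, needed a genome sequence and were not run.

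Peaks of the 4 libraries were merged into regions where they overlapped by at least 1 bp. A region was gained when a peak of the second library and none of the reference overlapped it, and lost in the opposite case. The measure of each comparison was the log2 ratio of regions gained to regions lost, with a 95% Wilson binomial interval. Chance overlap came from 100 random placements of the peaks on their own chromosomes. A gene was gained or lost by the same rule at its gene ends, over 19974 protein-coding genes. With 1 library per condition no test of 1 condition against another could be run and no p-value is given. A model of both agents over the 4 libraries, which has to assume that neither changes the effect of the other, was not run. The intervals cover counting error only, and neighbouring regions are not independent.

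Before the data were examined, 14 gene lists were fixed: estrogen response, luminal identity, PI3K-AKT-FOXO, KMT2 and partner complexes, SMYD family, cell cycle, apoptosis, ribosomal proteins, mitochondrial translation, ATF4 stress response, immediate early, basal and mesenchymal, genes of unrelated tissues, and HOX genes. All of their symbols were found in the reference. The number of list members with a gene end peak was set against 10000 random lists of the same size, matched on peak status in the reference library for a comparison, and its percentile describes these libraries only. The rule for named genes was fixed at the same time. It names 14 genes in every library, the list genes gained or lost with the highest −log10 q (up to 8 each way for doxycycline and 5 for alpelisib), and the 5 gained and 5 lost regions of each comparison with the highest −log10 q and no peak of the other library within 1 kb.

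No read totals came with the lists, so depth was recovered from the MACS2 values. The deposited fold and −log10 p of a summit together fix the whole number of fragments over it and the background expected there. Both were solved for each peak and matched the deposited −log10 p within 0.001 for 100% of peaks in each library. The genome-wide background, proportional to the depth of the library, was 1.177 fragments for vehicle, 0.95 for doxycycline, 0.876 for alpelisib and 1.235 for both agents. The median summit held 10 fragments in the vehicle library, 9 in the doxycycline library, 9 in the alpelisib library and 10 in the library with both. A summit of 10 fragments carries a wide counting error, so a peak present in 1 library and absent from another is weak evidence for a difference at that site alone. The control had 4.10 fragments per position behind each of the 4 lists. The labels do not say which of the 2 input samples it was, and the lists alone do not show that it was one of them, so the deposited folds rest on a control that could not be checked.

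The region counts and the recovery of fragments were tested on simulated data. All 200 regions planted as gained and all 200 planted as lost in the vehicle list of 58030 peaks were found, and fragments and background were recovered for 100% of 19098 simulated summits. Alternatives fixed beforehand were a fold of at least 4, a −log10 q of at least 5, equal numbers of peaks per library, other rules of overlap, a 5 kb window at gene ends, and leaving out chromosomes 1, 17 and 20. Peaks over 10 kb, a summit of at least 10 times the background, and a rule based on expected fragments were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.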

Results

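KMT2D, a methyltransferase that places monomethyl marks on lysine 4 of histone H3 at enhancers and promoters, was mapped in MCF7 cells in 4 conditions. Doxycycline induced a hairpin against SMYD2, another lysine methyltransferase, and alpelisib inhibited the alpha isoform of PI3 kinase. Each condition had 1 library and hence no replicate, so no difference below could be set against the spread between replicates. The vehicle list held 58030 peaks, the doxycycline list 77997, the alpelisib list 70261 and the list with both agents 48527. The peaks covered 24.3, 32.2, 31.8 and 22.8 Mb in that order, with median widths of 277, 280, 301 and 297 bp. The recovered genome background, proportional to depth, was 1.177, 0.95, 0.876 and 1.235 fragments, so the 2 libraries with the most peaks were the shallower ones.

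KMT2D peaks were found at gene ends far more often than random placement gave. Protein-coding genes with a gene end peak numbered 7898 in the vehicle library, 11244 with doxycycline, 12052 with alpelisib and 8687 with both agents, against means of 2016, 2640, 2482 and 1734 at random. Of the peak summits, 16.6% (95% Wilson interval 16.3 to 16.9) lay at gene ends in the vehicle library, 18.3% (18.01 to 18.6) with doxycycline, 20.97% (20.7 to 21.3) with alpelisib and 20.9% (20.6 to 21.3) with both. Gene bodies held 39.7%, 41.3%, 40.4% and 36.7% of the summits, and intergenic sequence held 43.7%, 40.4%, 38.6% and 42.4%.

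Peaks were crowded into a few blocks of the genome in all 4 libraries. Chromosomes 1, 17 and 20 together held 33.9% of the vehicle peaks, 29.1% of the doxycycline peaks, 29.6% of the alpelisib peaks and 35.5% of those with both agents. The bin from 48000001 to 49000000 on chromosome 20 held 746, 758, 788 and 848 peaks, and the bin from 64000001 to 65000000 on chromosome 3 held 818, 806, 797 and 685. The median bin of 1 Mb held 7, 11, 10 and 6 peaks. Some crowded bins went the other way, with more peaks in the vehicle and combined libraries. The bin from 27000001 to 28000000 on chromosome 20 held 243, 68, 54 and 151, and that from 92000001 to 93000000 on chromosome 3 held 119, 25, 28 and 75. Peaks wider than 10 kb numbered 50, 46, 41 and 60, and 47 of those in the vehicle library lay on chromosomes 17 and 20.

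**Figure D1:**
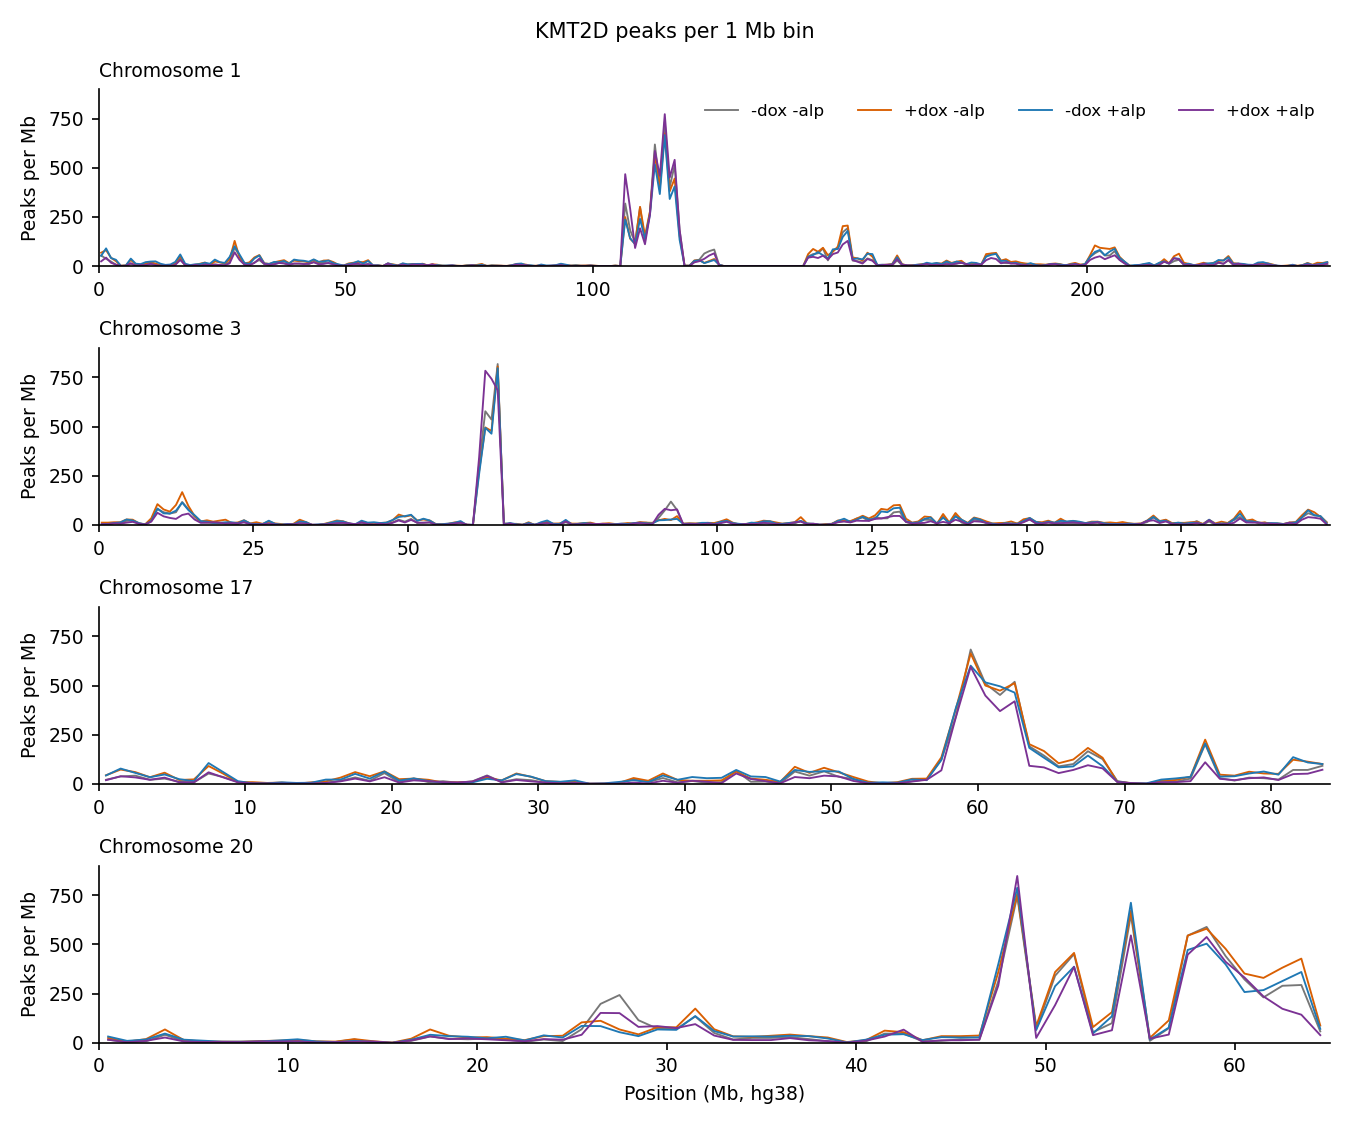
Number of KMT2D peaks (vertical axis) in bins of 1 Mb along chromosomes 1, 3, 17 and 20 (horizontal axis, Mb in hg38), with 1 line per library (dox, doxycycline; alp, alpelisib). The most crowded blocks stand out in all 4 libraries, such as the bin at 48000001 to 49000000 on chromosome 20 with 746 to 848 peaks. Other bins differ between libraries, such as 27000001 to 28000000 on chromosome 20, with 243 peaks with vehicle, 68 with doxycycline, 54 with alpelisib and 151 with both.

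SMYD2, the target of the hairpin, lies at 214281159 to 214337131 on chromosome 1 and had a gene end peak in each library, with deposited folds of 4.59 in the vehicle list, 4.10 with doxycycline, 5.86 with alpelisib and 5.82 with both. A peak there reads KMT2D occupancy and not SMYD2 transcript, so these lists hold no check of the knockdown. KMT2D itself, at 49018978 to 49060794 on chromosome 12, also had a gene end peak in each library. So did FOXA1, a pioneer factor of luminal cells, the estrogen-responsive genes GREB1, TFF1, MYC and CCND1, and IRS2 and ERBB3, which feed into PI3 kinase. FOXA1 carried the highest deposited fold among the 14 fixed genes in every list, at 16.5, 18.97, 30.9 and 18.8.

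The other fixed genes differed between libraries. GATA3, a luminal transcription factor, had a gene end peak with doxycycline alone and with alpelisib alone, and within 10 kb of the gene it had 5, 12, 16 and 10 peaks in the 4 libraries. PGR, the progesterone receptor, and PBX1, a homeodomain transcription factor, had a gene end peak with alpelisib alone, each in a summit of no more than 10 fragments. XBP1 had one in every library except vehicle. ESR1, the estrogen receptor gene, had none at its annotated ends, but 12, 12, 17 and 6 peaks lay within it or within 10 kb of it.

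The first comparison asked how SMYD2 knockdown changed KMT2D binding without alpelisib. With doxycycline, 43112 regions were gained and 23971 lost, a log2 ratio of 0.85 (95% interval 0.82 to 0.87). Another 26962 regions were shared, 28.7% of those in either library, against 1.77% at random. At gene ends 3969 genes were gained and 623 lost, a log2 ratio of 2.67 (2.55 to 2.79). This larger ratio need not be a larger change, since a ratio of gained to lost grows where less is lost. Of the vehicle library, 7275 of 7898 genes were kept, against 26962 of 50933 regions. In number, genes went from 7898 to 11244 and regions from 50933 to 70074.

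Among the 14 lists, 73 genes were gained and 16 lost in this comparison. The strongest gain was PTEN, the phosphatase that opposes PI3 kinase, with a peak at 87862328 to 87862635 on chromosome 10 that had a deposited fold of 9.74 and a −log10 q of 14.7. That peak lay outside the gene, which spans 87863625 to 87971930, and reached only the outer edge of the 1 kb window. The PTEN peak gained with alpelisib alone, at 87863274 to 87864102, was another one. HOXD8, the mitochondrial ribosomal gene MRPL2, the laminin gene LAMC2, the early growth response gene EGR3, XBP1, RPS18 and the mitotic cyclin CCNB1 followed, with −log10 q from 11.1 down to 7.64. The strongest losses were HOXC8, the mitochondrial protease LONP1, CD19, RPS6, MTIF2, PCNA, MRPS7 and RHO, with −log10 q from 7.57 down to 3.57. With a 5 kb window EGR3, HOXC8, LONP1, CD19, MTIF2 and PCNA had a peak in both libraries, and with summits of at least 10 times the background only HOXC8 and LONP1 of these 8 losses were left. CD19 and RHO belong to the list of unrelated tissues, as markers of B cells and photoreceptors. Estrogen response genes went from 22 to 30 of 36 with a gene end peak, with 8 gained and 0 lost, at percentile 98.995 of random lists matched on the vehicle library, or 87.8 with summits of at least 10 times the background. The match is on peak status only, so a list bound well in every library can stand high whatever the agent. Without matching this list was at percentile 99.5 in the vehicle library. A match on the other libraries was run only for alpelisib alone. Luminal identity genes went from 18 to 23 of 28 (percentile 94.9, but 97.8 with a 5 kb window at gene ends, 97.6 with equal numbers of peaks and 99.6 with summits of at least 10 times the background), and basal and mesenchymal genes from 5 to 13 of 25 (percentile 79.6). PI3K-AKT-FOXO genes went from 24 to 29 of 38 (percentile 84.7, and 99.2 with summits of at least 10 times the background).

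Genome-wide, the strongest region gained with doxycycline lay at 18788437 to 18788792 on chromosome 3, in intergenic sequence 343 kb from the nearest gene end, that of SATB1, with a deposited fold of 14.9. The next were inside PLXNB2 on chromosome 22, at NECTIN4 on chromosome 1, at 98819406 to 98819943 on chromosome 14 in intergenic sequence 349 kb from BCL11B, and at SLC43A2 on chromosome 17, with folds from 13.8 down to 11.8. The strongest lost regions were of another kind. Those at 80262936 to 80263244 on chromosome 18, 133264978 to 133265293 on chromosome 12 and 630856 to 631256 on chromosome 1 had low folds of 3.35, 3.22 and 2.72 over 87, 89 and 115 fragments. Those on chromosomes 18 and 12 lay close to chromosome ends, and the one on chromosome 1 lay inside LOC102724250. The remaining lost regions were inside CLCN5 on chromosome X and inside BCAS3 on chromosome 17, the latter in one of the blocks crowded with peaks. Keeping equal numbers of peaks per library, which by construction brings gained and lost regions close to each other, left a log2 ratio of 0.042 for regions and 1.70 for gene ends. Requiring summits of at least 10 times the background, chosen after seeing the data, gave 1.6 and 3.75. This cut is a multiple of the background of each library, so it asks for fewer fragments in the shallower single-agent libraries. Part of these larger ratios can come from the cut itself.

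**Figure D2:**
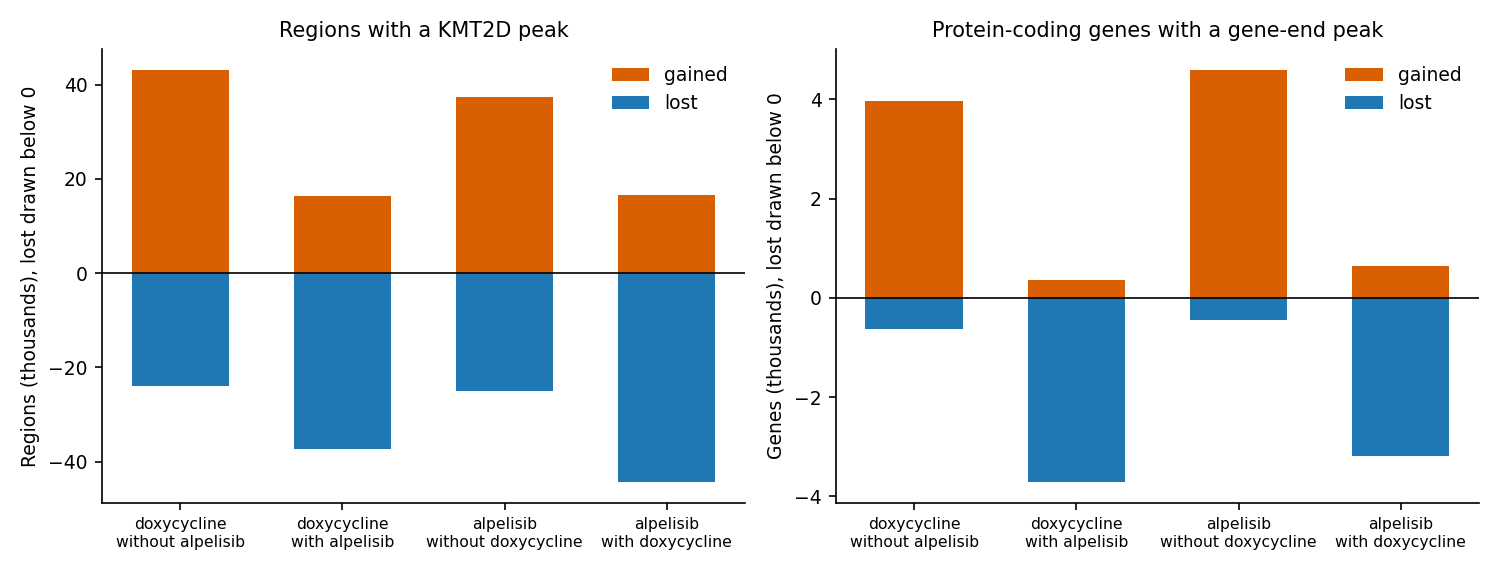
Regions (left, in units of 1000) and protein-coding genes with a gene end peak (right, in units of 1000) gained, drawn above 0, and lost, drawn below 0, in each of the 4 comparisons of 1 library with 1 library. Gains outnumber losses for each agent alone (43112 against 23971 regions for doxycycline) and losses outnumber gains for each agent on top of the other (37303 against 16282 regions for doxycycline with alpelisib).

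The second comparison asked the same of cells under alpelisib. Here adding doxycycline lost more than it gained, with 16282 regions gained, 37303 lost and a log2 ratio of −1.20 (−1.22 to −1.17). The 26030 shared regions made up 32.7%, against 1.59% at random. At gene ends 351 genes were gained and 3716 lost, a log2 ratio of −3.40 (−3.56 to −3.25).

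List genes followed, with 11 gained and 80 lost. The strongest loss was ELF3, an epithelial transcription factor of luminal cells, whose alpelisib-library peak at 202018164 to 202019481 on chromosome 1 had a fold of 13.9 and a −log10 q of 25. That peak lay outside the gene, which spans 202010587 to 202017183, and reached only the outer edge of the 1 kb window. TFAM, which maintains mitochondrial DNA, the apoptosis inhibitor BIRC2, the phosphatase DUSP5, the receptor ERBB4, CCNB1, the mTOR regulator TSC2 and MRPS15 followed, with −log10 q from 11.6 down to 8.91. The strongest gains were HOXA1, PPP1R15A, RPL5, NEUROD1, RPS23, RHO, CDK6 and BIRC5, all with low −log10 q of 5.38 down to 2.79. With a 5 kb window ELF3, PPP1R15A, NEUROD1 and CDK6 had a peak in both libraries, and with summits of at least 10 times the background 0 of these 8 gains were left. That cut asks for the most fragments in the library with both agents, where these gains lie. Luminal identity genes went from 27 to 17 of 28, with 0 gained and 10 lost, at percentile 23.4 of random lists matched on the alpelisib library, but 97.3 with a 5 kb window. Estrogen response genes went from 32 to 26 of 36 (percentile 91.7, and 99.3 with a 5 kb window), and PI3K-AKT-FOXO genes from 32 to 26 of 38 (percentile 90.9, and 99.6 with summits of at least 10 times the background). Immediate early genes, the first to respond to growth signals, went from 24 to 22 of 27, at percentile 99.2, which was 96.45 with a 5 kb window and 96.8 with equal numbers of peaks.

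The strongest region lost in this comparison, at 49658195 to 49660593 on chromosome 5, was intergenic, 736 kb from EMB, with a fold of 6.10 over 241 fragments. That many fragments at that fold place its local background far above the genome level, so the control piles up there too. The next were inside RNF213 on chromosome 17, inside TESC on chromosome 12, at 39744919 to 39745297 on chromosome 9, 383 kb from SPATA31A1, and at LGALS3 on chromosome 14, with folds from 14.4 down to 12.3. The strongest gained regions were intergenic and lay on chromosomes 17, 7, 2, 3 and 14. The nearest gene ends were those of WSB1, ADCYAP1R1, LOC124905368, ADAMTS9 and OR11H12, and the region near ADAMTS9 was in the crowded block of chromosome 3. WSB1 and OR11H12 were 834 and 1130 kb away. The chromosome 17 region lay in a bin with 43, 32, 26 and 41 peaks in the 4 libraries, more with vehicle and with both agents. The region on chromosome 2 had a low fold of 2.76 over 94 fragments. Equal numbers of peaks left a log2 ratio of −0.086 for regions and −2.01 for gene ends. With summits of at least 10 times the background these were −3.36 and −6.43.

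The third comparison asked what alpelisib did to KMT2D binding without the hairpin induced. Alpelisib gained 37348 regions and lost 24948, a log2 ratio of 0.58 (0.56 to 0.61), with 25985 shared (29.4%, against 1.73% at random). At gene ends 4596 genes were gained and 442 lost, a log2 ratio of 3.38 (3.24 to 3.52).

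Luminal identity had the highest percentile of the 14 lists in this comparison. It did not have the highest with a 5 kb window, equal numbers of peaks or summits of at least 10 times the background. Of its 28 genes, 27 had a gene end peak with alpelisib and 18 without, with 9 gained and 0 lost, at percentile 99.97 of matched random lists, or 95.4 with equal numbers of peaks. Estrogen response genes went from 22 to 32 of 36 (percentile 99.8), and mitochondrial translation genes from 15 to 25 of 32 (percentile 97.505, or 97.1 with equal numbers of peaks). Genes of unrelated tissues went from 10 to 11 of 32, at percentile 0.16, or 3.3 with a 5 kb window. PI3K-AKT-FOXO genes went from 24 to 32 of 38, at percentile 97.1, which was 99.8 with a 5 kb window, 99.2 with equal numbers of peaks and 99.3 with summits of at least 10 times the background. Over the 14 lists and 4 comparisons, 7 of 56 percentiles lay in the outer 2.5% at either end, where chance would give 2.8. List genes gained numbered 88, led by HOXD8, PTEN, SMYD4, RPS18 and DUSP6, with −log10 q from 16.7 down to 15.4. The 10 lost were led by CDK6, CD19, PPP1R15A, RHO and CDC6, with −log10 q from 6.55 down to 3.21. With a 5 kb window DUSP6, CDK6, CD19, PPP1R15A and CDC6 had a peak in both libraries, and with summits of at least 10 times the background only CDK6 of these 5 losses was left.

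The strongest region gained with alpelisib was the one at 49658195 to 49660593 on chromosome 5 that was absent with both agents and had a local background far above the genome level. Next came the region at 98819406 to 98819943 on chromosome 14, also gained with doxycycline alone, with a fold of 19.2, and regions beside ANXA11 on chromosome 10, 12.1 kb from VIPR1 on chromosome 3 and at PPP3CB on chromosome 10. Of the 5 strongest lost regions, those at 124714750 to 124715184 on chromosome 1, 48689485 to 48689930 on chromosome 5 and 26225528 to 26226082 on chromosome 19 lay more than 1 Mb from any gene end. Their folds of 8.33, 8.27 and 7.75 over 48, 31 and 29 fragments also place the local background above the genome level. The bin of the first held 84, 36, 31 and 65 peaks in the 4 libraries, again more with vehicle and with both agents. The other lost regions were the one at 630856 to 631256 on chromosome 1 and one inside DHX40, in the crowded block of chromosome 17. A −log10 q of at least 5 moved the log2 ratio of regions to 0.97 and equal numbers of peaks moved it to 0.072, while gene ends were at 2.81 with equal numbers. With summits of at least 10 times the background the ratios were 2.36 for regions and 6.03 for gene ends.

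The fourth comparison added alpelisib to cells with the hairpin induced. Losses again prevailed, with 16588 regions gained, 44350 lost and a log2 ratio of −1.42 (−1.44 to −1.39), and 25724 shared (29.7%, against 1.63% at random). At gene ends 637 genes were gained and 3194 lost, a log2 ratio of −2.33 (−2.45 to −2.20).

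List genes lost numbered 59 and those gained 11. ELF3 was again the strongest loss, with a fold of 11.3, followed by MRPS27, TSC2, the mucin gene MUC1 and EGR3. Its doxycycline-library peak, at 202017737 to 202019120, also lay outside the gene. The strongest gains were RBBP5, a core subunit of KMT2 complexes, MTIF2, RPS3, RPS6 and TXNIP, a regulator of glucose uptake, with −log10 q from 8.36 down to 5.05. With a 5 kb window ELF3, MUC1, EGR3, RBBP5, MTIF2 and TXNIP had a peak in both libraries, and with summits of at least 10 times the background TXNIP had one in neither. Genes of KMT2 and partner complexes stayed at 14 of 19, with 1 gained and 1 lost, at percentile 97.9 of matched random lists, which was 96.1 with a 5 kb window and 96.6 with equal numbers of peaks. Luminal identity genes went from 23 to 17 of 28 (percentile 52.0, but 99.3 with a 5 kb window), PI3K-AKT-FOXO genes from 29 to 26 of 38 (percentile 96.7, but 97.8 with a fold of at least 4 and 99.4 with summits of at least 10 times the background) and HOX genes from 21 to 13 of 32 (percentile 10.9).

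The strongest gained regions of this comparison were inside CUX1 on chromosome 7, inside POC1B on chromosome 12, inside NOXRED1 on chromosome 14, 4.76 kb from SPTSSB on chromosome 3, and inside GREB1 on chromosome 2 at 11539507 to 11540021, with folds from 14.3 down to 12.1. The strongest lost regions were 28.2 kb from GRAPL on chromosome 17, at PYCR1 on chromosome 17, inside PCNX1 on chromosome 14, at SSTR5 on chromosome 16, and at 34573851 to 34574518 on chromosome 16 with a low fold of 2.43 over 154 fragments. Equal numbers of peaks left a log2 ratio of −0.049 for regions and −0.63 for gene ends. A −log10 q of at least 5 gave −0.89 for regions, and summits of at least 10 times the background gave −2.42 and −3.72.

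Across all 4 libraries, 130127 regions had a peak in at least 1. Of these, 17404 (13.4%) were in every library and 80379 (61.8%) in a single one. The 20375 regions in exactly 2 libraries split by condition. Regions of the libraries that shared their doxycycline status numbered 4932 (24.2%), and regions of those that shared their alpelisib status numbered 6215 (30.5%). The crossed pairs held the largest number, 9228 (45.3%), of which 7259 were in the libraries with a single agent and 1969 in the vehicle library and the one with both. With equal numbers of peaks the crossed share was 40.1%. It was 68.1% with summits of at least 10 times the background, a cut that asks for fewer fragments in the single-agent libraries.

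**Figure D3:**
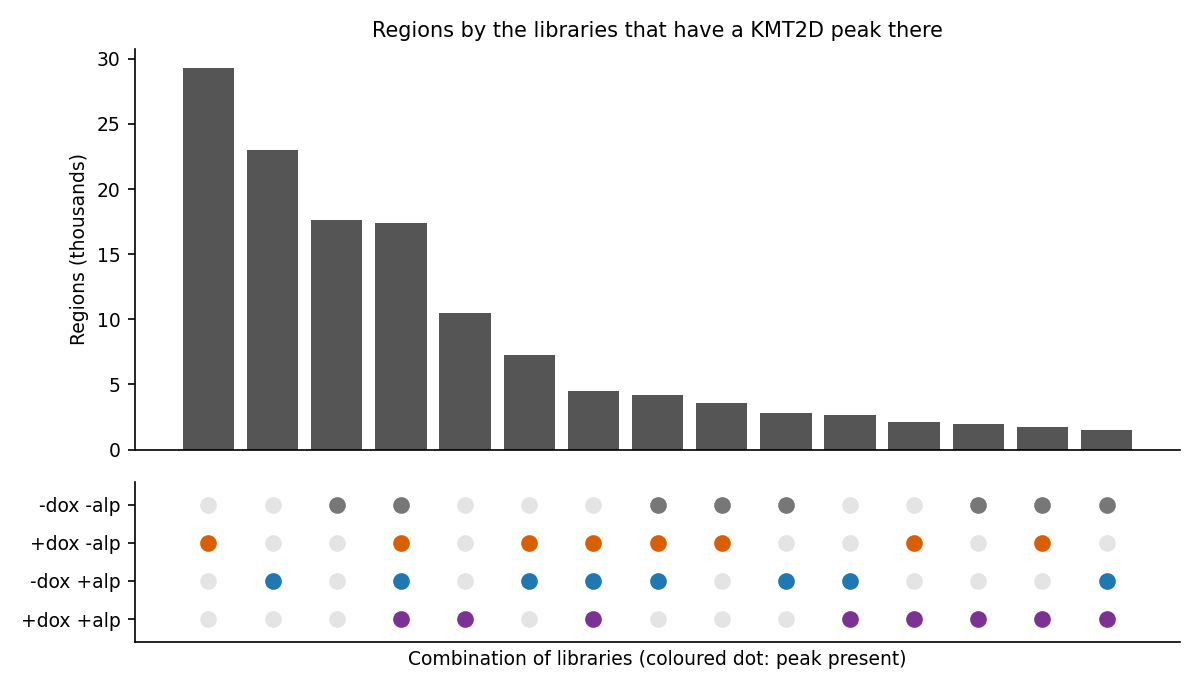
Number of regions (vertical axis, in units of 1000) for each of the combinations of libraries in which a KMT2D peak was present; coloured dots below each bar mark the libraries (dox, doxycycline; alp, alpelisib). Regions of a single library form the tallest bars apart from the 17404 regions of all 4, and the most frequent pair is doxycycline alone with alpelisib alone (7259 regions).

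Set against all protein-coding genes, 4 lists had gene end peaks more often than most random lists of their size in every library, at percentiles of at least 96.6. These were estrogen response (22, 30, 32 and 26 of 36 genes in the vehicle, doxycycline, alpelisib and combined libraries), luminal identity (18, 23, 27 and 17 of 28), PI3K-AKT-FOXO (24, 29, 32 and 26 of 38) and immediate early genes (22, 25, 24 and 22 of 27). KMT2 and partner complexes had 12, 14, 16 and 14 of 19, the SMYD family 3, 4, 4 and 4 of 5, and the ATF4 stress response 13, 16, 16 and 12 of 21. Cell cycle genes had 18, 20, 22 and 15 of 30, apoptosis genes 12, 18, 18 and 13 of 25, ribosomal protein genes 14, 18, 25 and 17 of 34, and mitochondrial translation genes 15, 18, 25 and 15 of 32. HOX genes had 14, 21, 19 and 13 of 32. The lowest shares were those of basal and mesenchymal genes, with 5, 13, 14 and 8 of 25, and of genes of unrelated tissues, with 10, 14, 11 and 10 of 32.

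**Figure D4:**
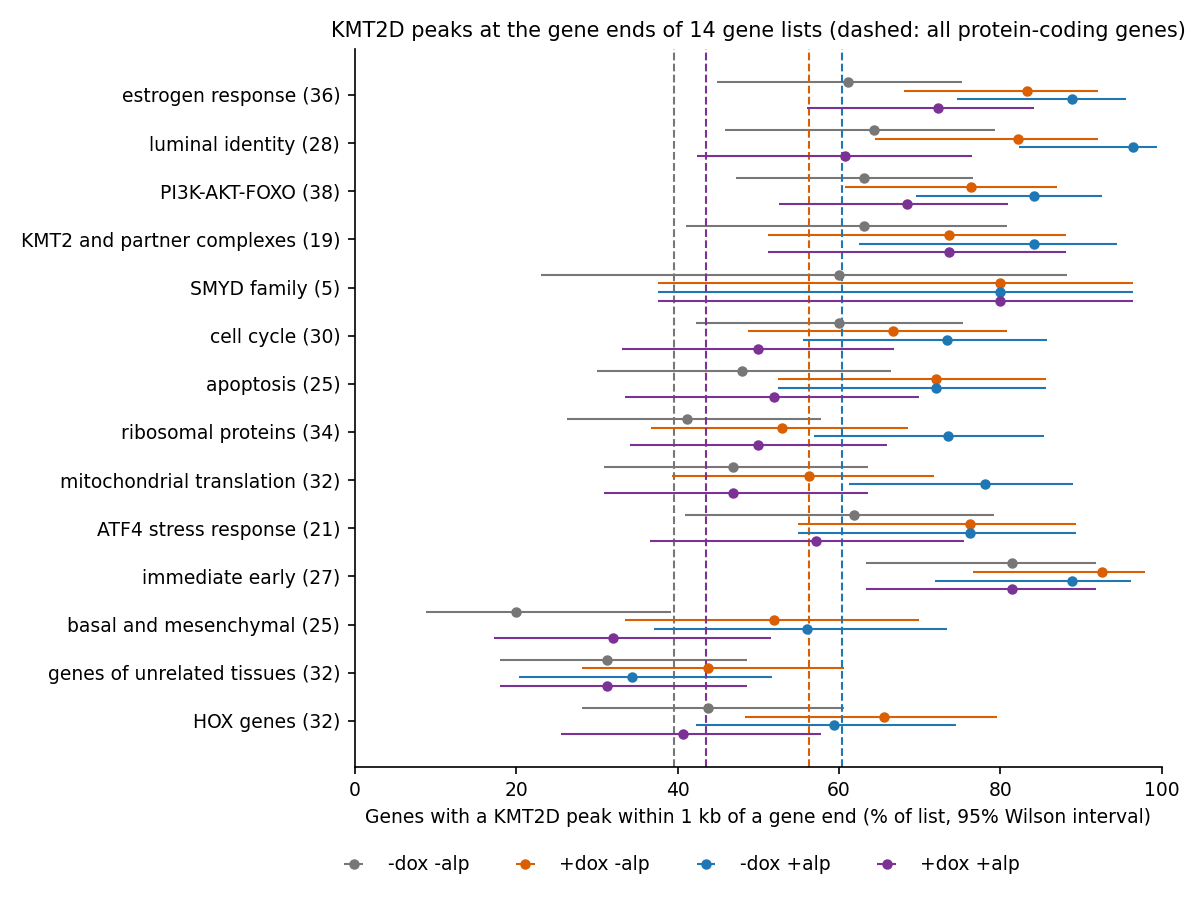
Share of the genes of each list with a KMT2D peak within 1 kb of a gene end (horizontal axis, percent; points with 95% Wilson intervals; list sizes in brackets), with 1 colour per library and dashed lines for all 19974 protein-coding genes. Luminal identity genes reached 96.4% with alpelisib alone, while genes of unrelated tissues stayed between 31.2% and 43.8%.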

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

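The tests of depth, input and a single enrichment factor in this part were chosen after the results were seen. Doxycycline and alpelisib each had opposite directions depending on the other agent, and these differences were not tested, since each rests on 1 library per condition. For regions, the log2 ratio of gained to lost was lower by 2.04 units for doxycycline with alpelisib than without (difference −2.04), and the alpelisib comparisons differed by −2.00 in the same sense. At gene ends the differences were −6.08 for doxycycline and −5.70 for alpelisib. A larger part of the gene ends than of the regions was shared, which alone widens such ratios. The values at gene ends therefore need not be larger changes.

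The pattern behind these values is that the libraries with neither or both agents had fewer peaks than those with a single agent. Deeper sequencing giving more peaks is argued against, since the library with the higher background had more peaks in only 1 of the 6 library pairs, and so are different input controls, since the scaled control background was equal within 2% at 100% of the 409 coinciding summits whose background lay above the genome level. A single factor of enrichment acting on all regions stays open: among regions of all 4 libraries the shift between single-agent and other libraries was larger at gene ends by 0.20 (log2, at matched enrichment, without chromosomes 1, 17 and 20), but only by 0.086 (SD 0.011 over 200 resamplings of chromosomes) to 0.14 over 9 ways of leaving out crowded bins and regions with a high control. Most of the shift was common to both kinds of region, at medians of 0.63 to 0.64 at gene ends and 0.48 to 0.53 elsewhere. However, summits were divided by the background of their library, which adds the same amount to every region. Most of the common part is that amount, so it is no sign of a single factor. The difference between gene ends and elsewhere is free of it. Efficiency of immunoprecipitation, the lower backgrounds of the single-agent libraries and condition therefore cannot be told apart with 1 library each. An interaction of SMYD2 knockdown with PI3 kinase inhibition, an effect of doxycycline itself, and GC bias remain untested.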

How the results depend on the processing

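Peaks over 10 kb, summits of at least 10 times the background and the rule on expected fragments were chosen after seeing the data. The other alternatives were fixed before. The cut at 10 times the background asks for fewer fragments in the shallower single-agent libraries. It kept 18219 vehicle, 29701 doxycycline and 39146 alpelisib peaks, and 14523 with both agents, so values under it are not independent of depth. A ratio above 0 only says that the second library had more regions or genes than the reference, so the direction for regions largely restates the numbers of peaks. Neither the region ratios nor the gene end ratios changed direction: 0 of 44 and 0 of 16 alternatives reversed, and 6 of each stayed inside the main interval. The cause of the moves was not tested, except that equal numbers of peaks by construction bring gained and lost regions close together. No replicate could be left out. No paired analysis was possible by replicate because each KMT2D condition had 1 library, and the CUT&RUN groups, which share replicate numbers, were not analysed. The KMT2D libraries could have been paired by their status for the other agent. That has to assume that neither agent changes the effect of the other, and it was not run. Motif shares and random lists matched on GC content were not run. Depth limits the calls: the median summit held 9 or 10 fragments, so an absent peak does not show absent binding.

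In what follows values are in the order doxycycline without alpelisib, doxycycline with alpelisib, alpelisib without doxycycline and alpelisib with doxycycline, and values inside the main interval are left out. The log2 ratio of regions gained to lost was 0.89, −1.36, 0.64 and −1.56 with a fold of at least 4. It was 0.042, −0.086, 0.072 and −0.049 with equal numbers of peaks, and 0.97, −1.44, 0.73 and −1.61 without chromosomes 1, 17 and 20. It was 1.00, −1.42, 0.69 and −1.66 with peaks within 1 kb merged, and 1.11, −1.68, 0.79 and −1.96 with a fold of at least 4 and no peak within 1 kb. With 50% reciprocal overlap it was 0.60, −0.76, 0.38 and −0.98. With summits of at least 10 times the background it was 1.6, −3.36, 2.36 and −2.42, and with at least 20 fragments expected at the other depth 1.62, −4.47, 4.40 and −2.52. That last rule left 148 regions gained and 48 lost, 23 and 510, 907 and 43, and 36 and 207. With a −log10 q of at least 5 the first comparison was at 0.79, the third at 0.97 and the fourth at −0.89, where gained and lost regions numbered 12543 and 7277, 14183 and 7256, and 6385 and 11845. With summits within 500 bp the last 3 comparisons were at −1.14, 0.55 and −1.39.

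At gene ends the log2 ratio was 1.70, −2.01, 2.81 and −0.63 with equal numbers of peaks (3012 gained and 927 lost, 693 and 2793, 4044 and 578, 1317 and 2036). With summits of at least 10 times the background it was 3.75, −6.43, 6.03 and −3.72. A 5 kb window moved the alpelisib comparisons to 3.16 and −2.45. The share of peaks at gene ends in the vehicle, doxycycline, alpelisib and combined libraries was 30.4%, 33.2%, 35.9% and 33.0% with a 5 kb window, and 17.8%, 19.6%, 22.5% and 22.95% with a fold of at least 4. With equal numbers of peaks it was 17.7%, 21.8% and 24.3% in the first 3.

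The percentage of regions shared was 29.4, 33.7, 30.1 and 30.6 with a fold of at least 4, 36.1, 40.5, 34.3 and 39.5 with a −log10 q of at least 5, and 31.7, 36.4, 31.6 and 33.7 with equal numbers of peaks. It was 25.3, 30.2, 26.5 and 26.6 without chromosomes 1, 17 and 20, 32.5, 37.0, 33.7 and 33.2 with peaks within 1 kb merged, and 33.7, 27.6, 27.5 and 33.4 with summits of at least 10 times the background. Among regions in 2 libraries, the share of those with the same doxycycline status was 21.2% with a −log10 q of at least 5, 25.3% with equal numbers of peaks, 23.5% without chromosomes 1, 17 and 20, 23.3% with peaks merged and 14.9% with summits of at least 10 times the background. The crossed share was 48.7%, 40.1%, 46.3%, 46.7% and 68.1% under the same settings. The share with the same alpelisib status was 34.6% with equal numbers and 17.04% with summits of at least 10 times the background.

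Of the percentiles of gene lists under the alternatives, 195 stayed inside or outside the outer 2.5% at either end as in the main result, 8 left it and 21 entered it, with 0 reversed. The 8 belonged to the estrogen response list for doxycycline without alpelisib, the immediate early list for doxycycline with alpelisib, the luminal identity, mitochondrial translation and unrelated tissues lists for alpelisib without doxycycline, and the list of KMT2 and partner complexes for alpelisib with doxycycline. Of the 21, 7 belonged to PI3K-AKT-FOXO, 5 to immediate early, 4 to luminal identity, 2 to estrogen response and 1 each to the SMYD family, unrelated tissues and HOX lists. The libraries with a gene end peak were the same for 48 of 51 named genes with a fold of at least 4, for 41 with equal numbers, for 32 with a 5 kb window and for 21 with summits of at least 10 times the background. Of the 52 gains and losses of single list genes named, 52 held with a fold of at least 4, 52 with equal numbers, 31 with a 5 kb window and 33 with summits of at least 10 times the background. The counts for a fold of at least 4 and for equal numbers were close to fixed in advance. Those settings only remove weaker peaks, and the genes were named for the highest −log10 q.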

Other observations

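The values from recovered fragments and the tests of copy number in this part were chosen after the peak comparisons were seen; the bounds for the tests of matched gene lists were written before its values. Summit fragments divided by the genome background allowed the level of shared regions to be set side by side. In the 5725 gene end regions of all 4 libraries the median summit was 10.2 times the background with vehicle, 13.7 with doxycycline, 18.3 with alpelisib and 10.5 with both. The median log2 ratio was 0.48 for doxycycline without alpelisib, −0.78 with it, 0.87 for alpelisib without doxycycline and −0.38 with it. In the 11679 shared regions elsewhere it was 0.23, −0.42, 0.32 and −0.30. Alpelisib alone thus stood highest. Of the shared gene end regions, 96.2% were higher with it than with vehicle. The single-agent libraries had the lower backgrounds, 0.876 with alpelisib and 0.95 with doxycycline. The division alone shifts every region by the log2 ratio of the backgrounds compared. Elsewhere that amount was larger in size than the median shift in all 4 comparisons, so those shifts can come wholly from the division. At gene ends it equalled the median shift for alpelisib with doxycycline. The remaining gene end medians were larger in size than it, so only part of them can come from the division.

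Of the 7456 genes with a gene end peak with vehicle and with alpelisib alone, 7158 were higher with alpelisib. FOXA1 had 29.7 times the background with vehicle (95% Poisson interval 20.7 to 41.4), 37.9 with doxycycline (26.5 to 52.5), 65.1 with alpelisib (49.3 to 84.3) and 33.2 with both (23.8 to 45.1). GREB1 had 13.6 (7.77 to 22.1), 18.9 (11.2 to 29.9), 34.3 (23.1 to 48.9) and 11.3 (6.20 to 19.03), and ERBB3 had 30.8 (20.3 to 44.8) with alpelisib alone against 14.4 (8.42 to 23.1) with vehicle. Of the 9 fixed genes with a gene end peak in every library, 7 were highest with alpelisib alone, IRS2 was highest with doxycycline alone and TFF1 with both agents. Before division by the background, SMYD2, 1 of these 7, held more fragments with both agents (12) than with alpelisib alone (10). The others of these 7 still held the most with alpelisib alone, but CCND1 only by 34 to 33 with doxycycline. GATA3, with no gene end peak in the other 2 libraries, had 11.6 with doxycycline alone and 11.4 with alpelisib alone. These intervals cover counting error only. Among list genes with a peak in both libraries, those of KMT2 and partner complexes had a median log2 ratio of 0.89 for doxycycline alone (11 of 11 genes higher, percentile 98.5 of random lists matched on level) and 1.25 for alpelisib alone (12 of 12, percentile 97.7), and PI3K-AKT-FOXO genes had 0.72 for doxycycline alone (percentile 98.4). Luminal identity genes had −0.21 for alpelisib with doxycycline (percentile 97.6). For doxycycline with alpelisib, basal and mesenchymal genes had −0.38 (percentile 97.53) and ATF4 stress response genes −1.05 (percentile 2.03). Of 50 such percentiles 6 lay in the outer 2.5% at either end, where chance would give 2.5.

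Gene end peaks gained with alpelisib alone could be more frequent among luminal genes because these were bound well in every library. Random lists matched on peak status in the other 3 libraries would then do as well, but the luminal identity list was at percentile 99.98 of them, with 27 genes against a random median of 22. It was again at 99.98 when the level of the peaks in those libraries was matched too. This argues against that explanation for binding strong enough to give a peak. No level could be matched for the 5 luminal genes without a peak in those libraries, 4 of which had one with alpelisib alone. Much of the excess can come from them, so for weaker binding the explanation stays open. The estrogen response list was at 96.98 and 96.76, so for it the explanation stays open. The lean was not particular to these lists, since mitochondrial translation was at 98.2 and 96.9, ribosomal proteins at 97.2 and 96.9, and genes of unrelated tissues at 0.21 and 0.68, and in level it did not stand out: among genes with a peak in both libraries the median log2 ratio for alpelisib was 1.09 in luminal identity genes (percentile 84.5 of lists matched on level) and 0.90 in estrogen response genes (42.9). GC content and other gene properties that need sequence were not examined, binding too weak for a peak could not be matched, and a response of luminal chromatin to PI3 kinase inhibition remains a hypothesis from 1 library.

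The blocks crowded with peaks could come from extra copies of those segments, since MCF7 is known to carry amplified segments on chromosomes 1, 3, 17 and 20. An accident of 1 library is argued against, since 17 of the 20 most crowded bins were common to all 4 libraries. If the ChIP DNA carried copy number that the control does not carry, the control would sit near its genome level there, and its median at the peaks over 10 kb on chromosomes 17 and 20 was 1 times that level, the lowest value the peak caller records, with a highest value of 1.71 to 2.44 by library, while the median summit held 50.2 to 69.6 times the background. In the most crowded bins on chromosomes 1 and 3 the median control was slightly above its genome level, at up to 1.12 times. On chromosomes 17 and 20 this is consistent with copy number missing from the control, which would also raise the deposited folds there and leaves in doubt whether the control was an input of these cells, although the lists measure no copy number and dense KMT2D binding stays open as a biological alternative.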
